A study of Homo sapiens with 8 samples.

How the data were processed

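Gene levels were measured by paired-end RNA-seq of mRNA from 8 stable A673 lines, 5 with an shRNA against EWS-FLI1 and 3 with an shRNA against luciferase. Per the labels' protocol, the mRNA fraction was converted to cDNA and uridine was digested before amplification, a step used in libraries that keep the strand. Per the submitters' processing notes, TopHat2 and the hg19 build were used. The counter, the annotation release, the gene length behind each value and whether counting used the strand are not given in the sources used here. The authors deposited RPKM values (reads per kilobase of gene per 1000000 mapped reads), with 1 column per library and 1 row per Ensembl gene. Columns were matched to samples by their titles, and lines were numbered within each group in the order of their records, so a number pairs no lines.

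The table held 18631 rows. In 24 rows the symbol had been turned into a date, and it was restored from the Ensembl identifier. Where a symbol repeated, the row with the highest mean over the 8 libraries was kept, which removed 30 rows. Of the identifiers, 17910 were found in the gene name table. Coordinates, gene types and exon lengths came from GENCODE release 29 on GRCh38, matched by Ensembl identifier for 17981 rows (96.51%). No coordinate of the build used for alignment was used or converted.

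RPKM are not counts, so no count model was applied. Depth was estimated from low values: between rows under 0.3 RPKM in both libraries, the commonest ratio of values gave the relative depth, which ranged from 1.00 to 1.38. With exon lengths, the totals that made low values whole reads were 14.6, 14.8, 15.9, 13.4 and 16.3 M reads (M, 1000000) for EWS-FLI1 shRNA lines 1 to 5 and 16.8, 12.2 and 14.3 M for control lines 1 to 3. Of 4896 rows under 100 reads in every library, 68.4% came out within 0.1 of a whole read in all 8 libraries. On simulated data of 12000 genes the largest error of a recovered total was 0.032%. No library was a copy of another: the highest correlation was 0.984, between control lines 1 and 3 (Pearson, across genes).

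The main test was limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with values as deposited, group as the only term and eBayes with a variance trend. Genes at 1 RPKM or more in at least 3 of the 8 libraries were tested, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A log2 change is on the log2(RPKM + 1) scale and understates the change of genes with low values. FLI1 and EWSR1 were also tested by an exact permutation of the difference in means over all 56 splits, with both tails, by doubling the smaller tail. In the text, "rose" and "fell" are used of genes past the threshold.

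The 21 gene lists were fixed from general knowledge before the data were examined, and the 18 with at least 5 tested genes were tested with camera at a preset correlation of 0.01. An estimated correlation and fry were run beside it. With the estimated correlation 0 lists passed, and with fry 4 passed (actin cytoskeleton and focal adhesion, both EWS-FLI1 target lists, and neural genes). The target lists draw on published studies of Ewing sarcoma cells, so some members may have been first described in this line. Fixed before the data were examined as well, the rule for named genes took FLI1 and EWSR1; the 10 highest and 10 lowest log2 changes among called genes with ranges apart and a mean of at least 5 RPKM in the higher group, without clone names; up to 4 members of each list by adjusted p; and any member of the target lists. The rule gave 130 genes, of which 60 are reported, picked after their values were seen. A further 17 genes outside the rule are said to be chosen after their values were seen. The alternatives and the search for libraries that stand apart cover these 77 genes.

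The fit was tested on simulated data with the real means and spreads of 14354 genes, 200 of them changed, for 5 against 3 libraries. It recovered 11.0% of genes set to a log2 change of 1 and 58.0% of those set to 2, and 2 of its 71 calls were wrong. The changed genes were drawn from those with a control mean above 2 on the log2(RPKM + 1) scale. A list of 15 genes moved by 1 was called, and none of the other lists were. Simulated genes varied independently of each other, while the estimated correlation within real lists reached 0.67 (extracellular matrix). The simulation therefore cannot show how often camera calls a real list wrongly.

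Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 RPKM, rescaling to a common sum (TPM), median-of-ratios scaling, quantile normalization, eBayes without trend, library weights (arrayWeights), and leaving out each library. A fit with each library's trend of values with exonic length removed was added after seeing the data. Lists were followed across alternatives by their median relative to all genes, a choice made after a first run that had used camera's direction. A test of control line 2 for admixed cells of the other group was also chosen after the data were seen, and its values are given with the observations. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures. Of the 77 genes reported, 36 have an exon that overlaps another gene in the annotation, so part of their reads may belong to that gene.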

Results

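RNA-seq was carried out on 8 stable lines made from A673, an established Ewing sarcoma cell line that carries EWS-FLI1, a fusion of the genes EWSR1 and FLI1 that acts as an aberrant transcription factor. In 5 lines a short hairpin RNA (shRNA) was directed at EWS-FLI1, and in 3 control lines the hairpin was directed at luciferase. The comparison asks which transcripts differ when the fusion is reduced. Each line gave 1 library, and the deposited values were RPKM for 18631 genes. The low values moved in steps of whole reads, which put the totals at an estimated 12.2 to 16.8 M reads (M, 1000000) per library. The labels name no clone, hairpin sequence, culture day or batch, and do not say whether the lines of a group arose separately. The p-values therefore measure only the spread between these libraries, part of which may be technical.

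The level of FLI1, which provides the DNA-binding part of the fusion, was lower in each of the 5 EWS-FLI1 shRNA lines than in any control line. FLI1 (ENSG00000151702, chromosome 11, 128686535 to 128813267 on GRCh38) stood at 5.60 ± 0.818 RPKM (SD, n = 5) against 9.72 ± 1.14 RPKM (SD, n = 3), which is 57.7% of the control mean. Line by line it was 6.25, 5.48, 5.76, 6.25 and 4.26 RPKM with the EWS-FLI1 shRNA and 9.38, 11 and 8.78 RPKM in the controls. The difference was -0.70 on the log2(RPKM + 1) scale (exact permutation test, both tails, p = 0.0357, the smallest that 56 splits allow). In the limma fit across all genes FLI1 did not pass, with an adjusted p of 0.148 (from 0.0149 with library weights, where it passed, to 0.466 over the alternatives). EWSR1 (ENSG00000182944, chromosome 22, 29268009 to 29300525), whose reads come from the normal gene as well as from the fusion, showed no detectable difference. It stood at 23.7 ± 3.78 RPKM (SD, n = 5) against 24.6 ± 0.829 RPKM (SD, n = 3), with p = 0.643 in the exact permutation test. The values are per gene, so fusion transcripts and any transcripts of the normal FLI1 gene were not separated.

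**Figure D1:**
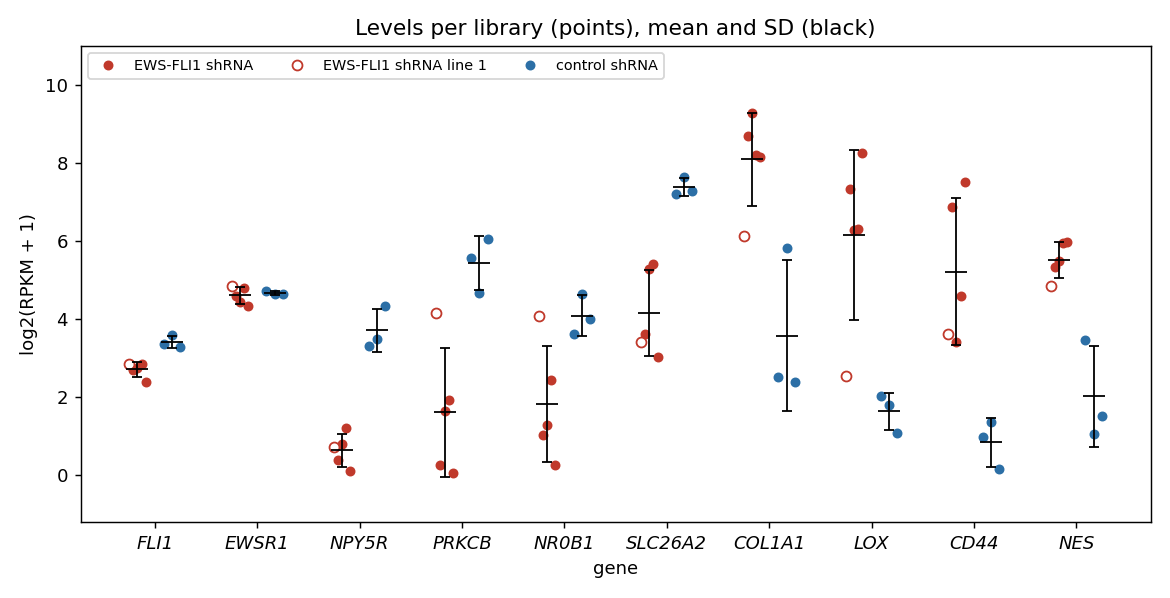
Level of 10 genes in each library on a log2(RPKM + 1) axis, with EWS-FLI1 shRNA lines in red (line 1 as an open circle) and control lines in blue; black bars give the mean and SD of 5 or 3 libraries. FLI1 lies lower in all 5 EWS-FLI1 shRNA lines, and line 1 lies near the controls for PRKCB, NR0B1 and LOX.

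Across the 14354 genes tested, 73 were higher and 224 were lower in the EWS-FLI1 shRNA lines (limma, adjusted p under 0.05). Of these 297 genes, 293 differed by at least 2-fold on the log2(RPKM + 1) scale. Each of the 297 had groups whose ranges did not overlap, which a call at this threshold favours, so it is not separate support. Ranges were apart for 13.7% of all tested genes, where chance gives 3.57% as an average over all splits. Genes vary together, so a single split can lie far from that average. At an unadjusted threshold of 0.05, limma gave 2398 genes. The median change of all tested genes was -0.12 (log2), and medians of gene lists are therefore given relative to it.

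The lower genes included several that fell from clear expression to near 0. GPR174, a receptor coupled to G proteins, fell from 62.4 ± 29.7 RPKM (SD, n = 3) to 0.855 ± 1.64 RPKM (SD, n = 5), a log2 change of -5.27 ± 0.55 (SE) with a limma adjusted p of 0.00271. XG, which encodes a blood group antigen, fell from 25.3 ± 12 to 0.397 ± 0.50 RPKM (log2 change -4.20 ± 0.36, limma adjusted p = 0.00176). SPHKAP, SLC35F3 and AMER2 fell from 16.7 ± 5.48, 15.1 ± 4.19 and 13.6 ± 5.09 RPKM to 0.438 ± 0.717, 0.331 ± 0.359 and 0.196 ± 0.365 RPKM. NPY, the neurotransmitter neuropeptide Y, was at 24.7 ± 20.5 RPKM in the controls and at 0.945 ± 1.39 RPKM in the EWS-FLI1 shRNA lines (limma adjusted p = 0.0304). PRKCB, a protein kinase C gene, had a log2 change of -3.83 ± 0.82 (limma adjusted p = 0.0478), with 16.9 RPKM in EWS-FLI1 shRNA line 1 and at most 2.81 RPKM in the other 4 lines. C21orf67 and the T cell receptor segment TRAV1-2 fell from 89.1 ± 39.6 and 70.8 ± 15.2 RPKM to 7.25 ± 6.0 and 6.78 ± 4.81 RPKM. AKR1C2 had a log2 change of -3.67 ± 0.75 but ranged from 5.62 to 99.2 RPKM among the controls, and its reads may be shared with near-identical AKR1C genes. Over 18 alternatives, the call of PRKCB was lost in 14 (limma adjusted p up to 0.255), of TRAV1-2 in 9, of AKR1C2 and NPY in 8 each and of C21orf67 in 4.

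Among the higher genes were products of the cell surface, the matrix and the cytoskeleton. COL1A1, a chain of type I collagen, rose from 21.5 ± 29.5 RPKM (SD, n = 3) to 338 ± 204 RPKM (SD, n = 5), a log2 change of 4.52 ± 0.87 (SE) with a limma adjusted p of 0.0340. Control line 2 held 55.6 RPKM of COL1A1 and the other 2 controls 4.76 and 4.26 RPKM. LOXL2, a collagen-crosslinking enzyme, rose from 2.10 ± 0.350 to 77.0 ± 54.9 RPKM (log2 change 4.32 ± 0.59, limma adjusted p = 0.0122). CD44, the hyaluronan receptor, rose from 0.901 ± 0.743 to 68.8 ± 77.7 RPKM (limma adjusted p = 0.0454), with 9.75 to 23.3 RPKM in lines 1, 3 and 4 and 117 and 183 RPKM in lines 2 and 5. CDH13, a cadherin without a cytoplasmic domain, rose from 0.0545 ± 0.0738 to 28.8 ± 20.3 RPKM. NES, which encodes the intermediate filament nestin, rose from 4.37 ± 5.01 to 46.7 ± 14.5 RPKM (limma adjusted p = 0.0142). S100A16, PMP22, TPM1, NBL1 and CHST2 completed the 10 highest, with log2 changes of 4.74, 4.46, 3.46, 3.33 and 3.23. Over 18 alternatives, the call of CD44 was lost in 10 (limma adjusted p up to 0.241), of TPM1 in 9, of COL1A1 in 8, of S100A16 and CDH13 in 7 each, of NBL1 and CHST2 in 4 each, of PMP22 in 3, and of LOXL2 and NES in 2 each.

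Most of the genes known to be activated by EWS-FLI1 were lower. Of 30 tested members of that list, 7 fell, none rose and 23 did not pass. Adjusted over the list alone, 19 were lower and 1, UPP1, was higher. The list's median stood 1.80 below that of all genes (a relative median of -1.80, camera adjusted p = 1.34e-10; adjusted p = 0.160 with an estimated correlation). NPY5R and NPY1R, receptors for neuropeptide Y whose exons overlap on opposite strands, had log2 changes of -3.07 ± 0.33 and -3.33 ± 0.59 (limma adjusted p = 0.00292 and 0.0266). SLC26A2, a sulfate transporter, fell from 167 ± 28.5 to 21.6 ± 16.8 RPKM. PAPPA, PPP1R1A, VRK1 and PRKCB were the other members that fell. NPY5R passed in all 18 alternatives, while the call of SLC26A2 was lost in 4, of NPY1R in 6, of PAPPA in 7, of PPP1R1A in 9, of VRK1 in 10 and of PRKCB in 14. NR0B1, NKX2-2 and GLI1, transcription factors of the fusion's program, did not pass, with limma adjusted p of 0.168, 0.131 and 0.137 and log2 changes of -2.27, -2.53 and -1.87. Without EWS-FLI1 shRNA line 1 all 3 passed (limma adjusted p = 0.0128, 0.0160 and 0.00818), as they did with library weights (0.00193, 0.00207 and 9.47e-04). The weights gave line 1 only 0.18, so these settings are not separate support. Each of the 3 genes was highest in line 1 within its group, so a pass without that line was favoured in advance. Their highest adjusted p over the alternatives were 0.50, 0.523 and 0.50. EWS-FLI1 shRNA line 1 held 16 RPKM of NR0B1, within the control range of 11.3 to 24.2 RPKM, and the other 4 lines held 0.195 to 4.40 RPKM. The mean log2 change over the list was -0.99 in line 1 and from -1.32 to -3.01 in the other 4 lines.

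Genes known to be repressed by EWS-FLI1 were mostly higher. Of 16 tested members, 2 rose, none fell and 14 did not pass, and 9 were higher when adjusted over the list alone. The relative median was 2.88 (camera adjusted p = 2.32e-09; adjusted p = 0.154 with an estimated correlation). IER3, a stress-response gene, rose from 12 ± 3.74 to 92.8 ± 43.0 RPKM, and ZYX, a focal adhesion protein, rose from 30.4 ± 1.5 to 99.5 ± 27.0 RPKM (limma adjusted p = 0.0136 and 0.0231), with their calls lost in 1 and 5 of 18 alternatives. LOX, a second collagen-crosslinking enzyme, stood at 126 ± 116 against 2.22 ± 0.987 RPKM but had a limma adjusted p of 0.0624, with 4.82 RPKM in line 1. PHLDA1 and THBS1 were higher in each EWS-FLI1 shRNA line than in any control but did not pass (limma adjusted p = 0.0782 and 0.148, log2 changes 3.57 ± 0.88 and 4.87 ± 1.50). IGFBP3 varied from 0.245 to 1045 RPKM among the 5 EWS-FLI1 shRNA lines and was at most 0.239 RPKM in the controls. The list's mean change was 0.54 in line 1 and from 2.22 to 3.40 in the other 4 lines.

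Extracellular matrix genes were higher as a group. All 17 tested members had positive changes, 3 of them rose, none fell, and 11 were higher when adjusted over the list alone. The relative median was 2.02 (camera adjusted p = 1.67e-11; adjusted p = 0.168 with an estimated correlation). COL4A1 and COL4A2, chains of basement membrane collagen, rose from 15.9 ± 4.04 and 41.7 ± 1.82 RPKM to 63.9 ± 21.4 and 121 ± 24.2 RPKM (limma adjusted p = 0.0231 and 0.0172), with their calls lost in 5 and 4 of 18 alternatives. BGN, the proteoglycan biglycan, stood at 729 ± 396 against 123 ± 30.8 RPKM, with a limma adjusted p of 0.0558. In line 1 the list's mean change was -0.15, against 2.24 to 3.04 in the other 4 lines.

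Actin cytoskeleton and focal adhesion genes also ran higher. Of 21 tested members, 3 rose (ZYX, TAGLN and TPM1), none fell, and 7 were higher when adjusted over the list alone. The relative median was 0.83 (camera adjusted p = 5.89e-10; adjusted p = 0.0928 with an estimated correlation). TAGLN, an actin-binding protein of contractile cells, rose from 3.42 ± 0.260 to 40.0 ± 26.8 RPKM, with the call lost in 7 of 18 alternatives. In line 1 the list's mean change was 0.56, against 0.73 to 1.39 in the other 4 lines. The YAP and TEAD target list had no member past the threshold over all genes and 4 higher when adjusted over the list alone. Its relative median was 1.31 (camera adjusted p = 8.74e-08; adjusted p = 0.160 with an estimated correlation). NT5E, an ecto-nucleotidase, stood at 209 ± 131 against 5.06 ± 2.95 RPKM (limma adjusted p = 0.0617). AMOTL2 and AXL had log2 changes of 1.78 ± 0.49 and 2.74 ± 0.77 (limma adjusted p = 0.106 and 0.114). CTGF stood at 34.2 RPKM in control line 2 and at 4.49 and 3.31 RPKM in the other 2 controls. Of 15 tested TGF-beta signalling genes 1 rose, the coreceptor ENG, from 12.4 ± 1.10 to 67.7 ± 33.0 RPKM, and the same 1 was higher when adjusted over the list alone. The call of ENG was lost in 8 of 18 alternatives. ID3, a target of BMP signalling, stood at 133 ± 48.6 against 49.9 ± 31.4 RPKM without passing (limma adjusted p = 0.148). The relative median of this list was 1.37 (camera adjusted p = 5.13e-06; adjusted p = 0.154 with an estimated correlation), and 0.81 without control line 2. Line 1 showed mean changes of 0.08 for the YAP and TEAD targets and 0.06 for TGF-beta signalling, below the other 4 lines in both.

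**Figure D2:**
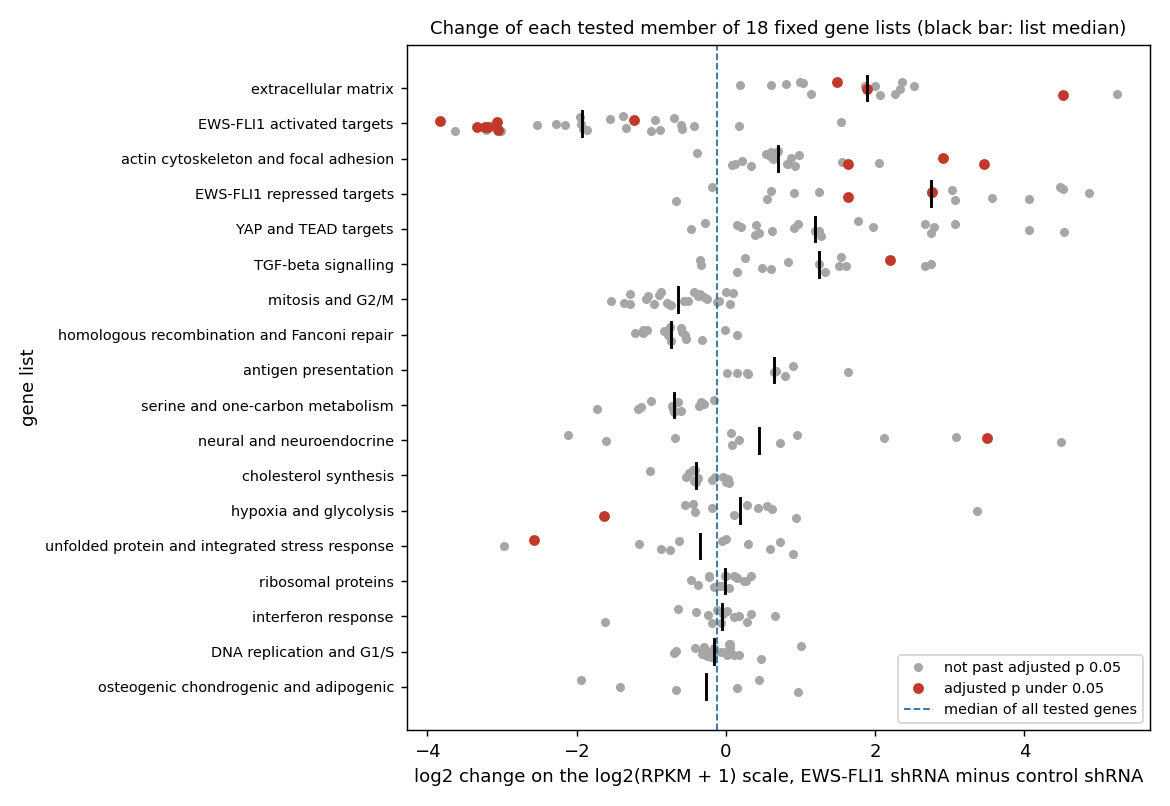
Log2 change (EWS-FLI1 shRNA minus control shRNA, on the log2(RPKM + 1) scale) of each tested member of 18 gene lists, with genes past an adjusted p of 0.05 in red, list medians as black bars and the median of all genes (-0.12) as a dashed line. All 17 extracellular matrix members lie above 0, and 28 of 30 activated targets lie below 0.

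The lists for mitosis, for homologous recombination and for serine metabolism ran lower. None of their members passed over all genes or over the list alone, and the mitosis and serine calls rested on single libraries. The 24 genes of mitosis and G2/M had a relative median of -0.52 (camera adjusted p = 0.00255; adjusted p = 0.406 with an estimated correlation), and without EWS-FLI1 shRNA line 3 the mitosis and G2/M list no longer passed. BUB1B, a spindle checkpoint kinase, stood at 37.4 ± 10.5 against 63.5 ± 8.61 RPKM (limma adjusted p = 0.197). The 15 genes of homologous recombination and Fanconi repair had a relative median of -0.61 (camera adjusted p = 0.00277; adjusted p = 0.406 with an estimated correlation). The mean change of the repair list was -0.17 in line 4, above control line 1 at -0.29. BRCA2 stood at 2.33 ± 1.37 against 6.12 ± 1.37 RPKM. The 13 serine and one-carbon metabolism genes all had negative changes and a relative median of -0.57 (camera adjusted p = 0.0157; adjusted p = 0.507 with an estimated correlation). This list did not pass without EWS-FLI1 shRNA line 3 or 4, or without control line 1 or 3 (values with the alternatives). Its mean change was 0.07 in line 1 and -0.45 in line 5, and control line 2 stood at -0.54, so the groups overlapped. PSAT1, an enzyme of serine synthesis, held 147 RPKM in line 1 and 17.8 to 42.6 RPKM in the other 4 lines, against 159 ± 68.5 RPKM in the controls.

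The 9 antigen presentation genes all had positive changes, a relative median of 0.77 and no member past the threshold over all genes or over the list alone (camera adjusted p = 0.00537; adjusted p = 0.406 with an estimated correlation). The list's mean change was -0.27 in line 1 and 0.01 in line 4, against 0.93 to 1.34 in lines 2, 3 and 5. HLA-C stood at 77.3 ± 33.5 against 38.4 ± 8.91 RPKM, and its reads may be shared with other HLA genes. Of 12 neural and neuroendocrine genes 1 rose, NES, and 4 were higher and 2 lower when adjusted over the list alone. GAP43 and L1CAM, genes of neurite growth, had log2 changes of 4.49 ± 1.02 and 3.08 ± 0.71 without passing over all genes (limma adjusted p = 0.0594 and 0.0607), and NEFM had 2.12 ± 0.50 (limma adjusted p = 0.0662). The relative median was 0.57 (camera adjusted p = 0.0157; adjusted p = 0.154 with an estimated correlation), and over the alternatives for the neural and neuroendocrine list the adjusted p of camera or fry ran from 0.00274 to 0.154. The relative median was 0.86 without EWS-FLI1 shRNA line 4 and 2.18 among genes with a mean of at least 5 RPKM. The call was lost without EWS-FLI1 shRNA line 1 (camera adjusted p = 0.104), with quantile normalization (0.0781), with library weights (0.114) and with the estimated correlation.

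The other 7 tested lists did not pass camera. Their adjusted p were 0.366 for cholesterol synthesis, 0.589 for hypoxia and glycolysis, 0.623 for the unfolded protein and integrated stress response, 0.623 for ribosomal proteins, 0.793 for the interferon response, 0.913 for DNA replication and G1/S, and 0.913 for osteogenic, chondrogenic and adipogenic genes. DNA replication and G1/S had a relative median of -0.03 while camera pointed upward. Camera asks for a shared direction. A form of fry that ignores direction gave adjusted p of 0.00493 for the stress response and 0.0494 for hypoxia and glycolysis. It gave 0.0904 or more for the rest of the 7 lists. In these lists 2 genes fell over all genes tested. VEGFA, the angiogenic growth factor, fell from 19.9 ± 1.25 to 5.97 ± 1.91 RPKM (limma adjusted p = 0.0250), and ASNS, asparagine synthetase, fell from 103 ± 63.9 to 14.1 ± 4.62 RPKM (limma adjusted p = 0.0352). Control line 2 held 32.1 RPKM of ASNS and the other 2 controls 156 and 121 RPKM. The call of ASNS was lost in 7 of 18 alternatives, among them leaving out control line 1 or 3 (limma adjusted p up to 0.211), and that of VEGFA in 4. Adjusted over the list alone, hypoxia and glycolysis had 1 higher gene (ADM) and 1 lower (VEGFA), the stress response 1 higher and 3 lower, osteogenic genes 1 lower, and the remaining 4 lists none. TRIB3 of the stress response stood at 9.12 ± 7.73 against 94.4 ± 79.6 RPKM (limma adjusted p = 0.0873), with 15.7 RPKM in control line 2. Blood cell and epithelial markers had 2 tested genes each, too few for a list test. CD79A of the blood list fell from 7.28 ± 2.10 to 1.03 ± 0.990 RPKM, a call lost in 8 of 17 alternatives, and both tested blood genes were lower when adjusted over the list alone. Neither epithelial gene passed in either way. Mitochondrially encoded transcripts were not analysed here.

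The number of genes past the threshold rested on single libraries. It was 764 without EWS-FLI1 shRNA line 1, 42 without line 2 and 116 without line 5, and it was 51, 130 and 26 without control lines 1, 2 and 3. On principal components of the tested genes, line 1 stood apart along the second component (32.0% of the variance), at 95.5 against -42.4 to -17.4 for the other 4 lines. Its deposited values summed to 349733 RPKM, against 257864 to 283064 RPKM in the other 7 libraries. The median SD over genes was 0.485 among the EWS-FLI1 shRNA lines and 0.214 among the controls (log2 scale).

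**Figure D3:**
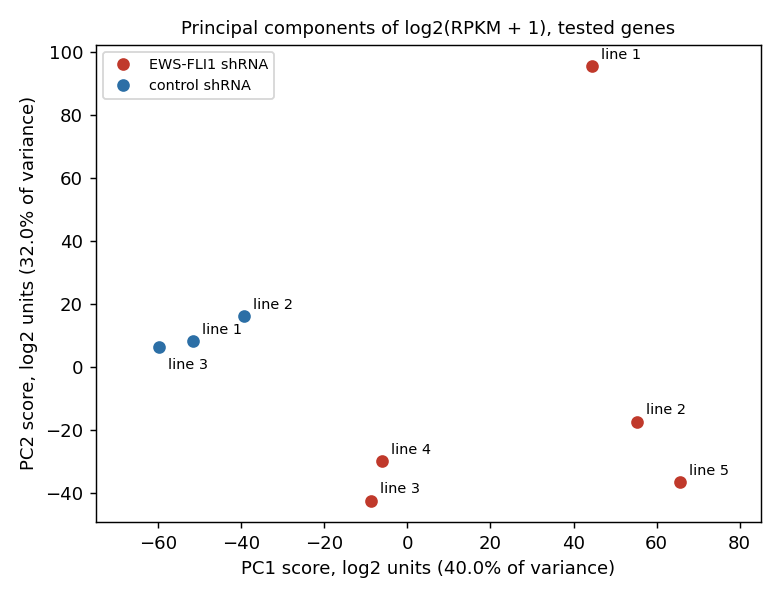
First (40.0% of the variance) and second (32.0%) principal component scores of the 8 libraries, from log2(RPKM + 1) of the 14354 tested genes, with EWS-FLI1 shRNA lines in red and control lines in blue. The 3 controls lie together, EWS-FLI1 shRNA lines 3 and 4 lie between them and lines 2 and 5 on the first component, and line 1 lies apart at 95.5 on the second.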

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

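The tests of depth and of transcript length in this part were chosen after the results were seen, and the counts over splits of the libraries were planned before. In the group of 5 EWS-FLI1 shRNA lines, 102 values were checked for a library far from the other 4, and 20 exceeded the limit. Chance gives about 1 in 20 for evenly spread values, but most of the 102 were RPKM of genes chosen after their values were seen, so no number expected by chance can be given. Of the 20, 11 were in line 1, 2 in line 2, 2 in line 3, 2 in line 4 and 3 in line 5. Groups of 3 were not checked.

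Line 1 stood apart most often. It held 16.9 RPKM of PRKCB, 5.06 of PPP1R1A, 16 of NR0B1, 16.8 of NKX2-2, 4.85 of GLI1, 0.845 of AMER2, 0.662 of PAX7 and 147 of PSAT1, each above the other 4 lines. Its mean change over the extracellular matrix list was -0.15, its values summed to 349733 RPKM, and its score on the second component was 95.5. FLI1 stood at 6.25 RPKM both in line 1 and in line 4, so its FLI1 level did not set it apart. Lower depth is argued against: line 1 had an estimated 14.6 M reads, above 3 other libraries. Short transcripts were over-represented in it (Spearman correlation of its deviation from the other 4 lines with exonic length -0.351, across genes). Once each library's length trend was removed, its root-mean-square deviation was 1.0, against 1.08 before and at most 0.706 in the other 4 lines, which argues against length as the whole cause. The design has no group within these lines, so no biological explanation was tested, and the origin of the difference stays open.

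In other lines, line 3 held 3.79 RPKM of GPR174 (the others at most 0.272) and 1.31 of AKR1C1 (at most 0.356). Line 4 held 1.70 RPKM of SPHKAP (at most 0.313) and 49.9 of L1CAM (at most 13.5). Line 2 held 1045 RPKM of IGFBP3 (at most 295) and 24.8 of NEFM (at most 11.5). Line 5 held 684 RPKM of THBS1 (at most 113), 91.0 of AXL (at most 29.2) and 95.9 of FOSL1 (at most 19.7).

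Over the 56 splits of the 8 libraries into 5 and 3, 2 gave as many genes as the real one (297), the real one included. A random grouping thus reaches that count in under 0.05 of the splits. The other of the 2 follows no label, so a high count does not by itself single out the study's groups. The same 2 splits gave as many genes higher in the group of 5 (73, the other 1099), lower in the group of 5 (224, the other 630) and genes changed at least 2-fold (293, the other 1180). These counts are therefore not separate evidence. For gene lists chance is not excluded: 13 of the 56 splits gave 11 or more lists, and the highest other split gave 14.

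The other split, which sets EWS-FLI1 shRNA lines 1, 2 and 5 against the remaining 5 libraries, gave 1729 genes (630 higher and 1099 lower in lines 1, 2 and 5), 5.82 times the real count, and so points to a structure of the samples that the labels do not name. Of the 297 called genes, 38 (12.8%) were also past the threshold there. That share is near the share of all tested genes called in that split (1729 of 14354). All 38 went in the same direction, which is favoured because lines 1, 2 and 5 belong to the EWS-FLI1 shRNA group. Depth is argued against as the cause of this structure. Control line 3 at 14.3 M reads lies next to lines 1 and 2, and line 3 at 15.9 M lies between lines 2 and 5. A shared length bias is argued against as well: with length trends removed that split still gave 1622 genes and the real one 327. Other measures of the libraries did separate these lines. Rows without reads numbered 798, 645 and 793 in lines 1, 2 and 5, against 336 to 444 in the other libraries. Their medians were 3.05, 4.05 and 3.86 RPKM, against 4.44 to 4.77 RPKM. Whether the lower number of detected genes is a cause or a result of this structure was not tested. No biological explanation was tested, because no label separates these lines.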

How the results depend on the processing

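The length correction and the choice of 60 genes were made after seeing the data, the other alternatives were planned, and the tests of scaling and spread were set after the higher and lower counts were seen but before their own results. FLI1 stayed lower in every alternative (log2 difference from -0.82 to -0.56). Its exact permutation p was 0.0357 in each alternative that changed its values with 8 libraries (the length correction was not put to this test) and, leaving out a library, 0.0571 or 0.0952, the smallest those designs allow, with differences from -0.77 to -0.62. EWSR1 turned positive at 0.067 with median-of-ratios scaling, at 0.0017 without line 5 and at 0.065 with the length correction, and its leave-one-out values ran from -0.13 to 0.0017.

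Counts moved by over 1.5 times in several settings. Given as higher, lower, both together, and changed at least 2-fold, they were 48, 69, 117 and 117 with a pseudocount of 0.1, 26, 33, 59 and 59 with a mean of at least 5 RPKM (fewer genes tested), 43, 116, 159 and 159 rescaled to a common sum, and 1224, 2087, 3311 and 1804 with library weights, which gave line 1 a weight of 0.18 and control line 3 of 4.67. Leaving out a library gave 1 to 309 higher, 25 to 455 lower, 26 to 764 together and 26 to 696 at least 2-fold changed, lowest without control line 3 and highest without EWS-FLI1 shRNA line 1. Beyond the smaller number of libraries, the cause was not tested. The number of lists was 0 with an estimated correlation, 4 with fry, and 9 to 11 in all others.

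Lower genes made up 75.4% of calls as deposited, 73.0% rescaled to a common sum, 66.0% with median-of-ratios scaling and 58.3% (108 higher, 151 lower) with quantile normalization. Scaling may account for part of this excess but did not end it. The median residual SD of genes at least 2-fold higher was 1.19 times that of genes at least 2-fold lower, so a larger spread may contribute too. Both values fell between the bounds set before these tests, so neither explanation was decided. The 2 were not tested against each other.

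The relative medians of the 11 called lists kept their sign, but some moved by over 1.5 times: TGF-beta signalling to 0.81 without control 2 and 0.89 without a filter, neural genes to 0.86 without line 4, 0.98 with a pseudocount of 0.1 and 2.18 with a mean of at least 5 RPKM, and antigen presentation to 1.21 with library weights. Lists not called changed sign as follows: interferon response -0.12 with a mean of at least 5 RPKM, -0.011 without line 2 and -0.069 without control 1 (leave-one-out highest 0.22); ribosomal proteins -0.14 with quantile normalization and -0.046 without line 1 (highest 0.24); DNA replication 0.069 with library weights, and 0.20, 0.028, 0.018 and 0.15 without lines 3, 4, 5 and control 2 (lowest -0.23); osteogenic genes 0.084 without line 1 and 0.068 without control 3 (lowest -0.41); cholesterol synthesis 0.049 without control 2 (lowest -0.35). Calls were lost for mitosis without line 3 (camera adjusted p = 0.0635) and for the list: serine and one-carbon metabolism without line 3 (0.109), line 4 (0.0957), control 1 (0.0605) and control 3 (0.0566). Among 60 genes named by the rule, 35 were called, of which GPR174, XG, SPHKAP, SLC35F3, AMER2 and NPY5R passed in all 18 alternatives and the others missed the threshold in 1 to 14. Of the 77 genes followed, the call was lost in 37, 2, 18 and 23 without lines 2, 3, 4 and 5 and in 35, 24 and 39 without controls 1, 2 and 3. Among the 77, 25 genes of the rule and FOS, EGR1, HMCN1, FOSL1 and TNFRSF12A had no call to lose. The losses are thus a larger share of the called genes than of the 77. Calls were also gained: 15 gained a call without line 1 and 27 with library weights, NR0B1, NKX2-2 and GLI1 in both, and FLI1 with library weights. A first run over all 130 genes of the rule also had sign changes for KIT, MYBL2 and CDKN1A, none of them called, which were not followed further.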

Other observations

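The genes below were chosen after their values were seen, and no group they belong to was tested. Of 3 transcription factor genes, OTX2 fell from 79.5 ± 26.1 RPKM (SD, n = 3) to 11.5 ± 6.19 RPKM (SD, n = 5), PAX7 from 3.36 ± 1.24 to 0.139 ± 0.292 RPKM and POU3F2 from 5.11 ± 3.35 to 0.485 ± 0.269 RPKM (limma adjusted p = 0.0144, 0.0136 and 0.0231), with calls lost in 3 of 18, 2 of 17 and 5 of 17 alternatives. ETS1, a member of the same transcription factor family as FLI1, rose from 0.568 ± 0.852 to 10.8 ± 7.17 RPKM (limma adjusted p = 0.0401), a call lost in 9 of 18 alternatives. AKR1C1 and AKR1C3 fell along with AKR1C2, with log2 changes of -2.64 ± 0.54 and -3.26 ± 0.50. Reads of these related genes may be shared between them, which was not tested, so the 3 values may not be independent. The call of AKR1C1 was lost in 9 of 17 alternatives (limma adjusted p from 0.00851 to 0.155) and that of AKR1C3 in 4 of 18 (limma adjusted p up to 0.0755), without EWS-FLI1 shRNA line 2 and without each control.

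Beside ASNS, 3 genes with roles in stress response or metabolism were chosen after their values were seen. ATF5 fell from 295 ± 199 to 24.9 ± 10.3 RPKM, CEBPG from 47.7 ± 14.2 to 18.4 ± 2.71 RPKM and PCK2 from 19.9 ± 13.9 to 1.28 ± 0.711 RPKM (limma adjusted p = 0.0317, 0.0377 and 0.0377), with calls lost in 7, 9 and 8 of 18 alternatives. Control line 2 held 65.9 RPKM of ATF5 and 4.09 of PCK2, against 402 and 418 and against 25.4 and 30.1 RPKM in the other 2 controls. The fixed stress response list did not pass camera (relative median -0.22, adjusted p = 0.623). Its relative median was -0.56 without control line 2 (camera adjusted p = 0.0904) and -0.038 without control line 1 (camera adjusted p = 0.964). It passed in no alternative, all of which tested a shared direction, with adjusted p of camera or fry from 0.0904 to 0.964. The form of fry that ignores direction gave an adjusted p of 0.00493.

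Beside TRAV1-2 (21642889 to 21643578 on GRCh38), 3 other genes of the T cell receptor alpha region on chromosome 14 were lower. OR4E2 (21653835 to 21667642 on GRCh38), an olfactory receptor gene, fell from 8.74 ± 2.84 to 0.510 ± 0.488 RPKM. TRAV3 (21723713 to 21724321) fell from 6.43 ± 1.07 to 0.378 ± 0.425 RPKM, and TRAV39 (22304054 to 22304553) was at 4.30 ± 2.51 RPKM in the controls and listed at 0 in all 5 EWS-FLI1 shRNA lines. Their limma adjusted p were 0.00464, 0.00427 and 0.0136. OR4E2 passed in all 17 alternatives, TRAV3 missed the threshold with a pseudocount of 0.1 (limma adjusted p = 0.0506), and TRAV39 missed it without EWS-FLI1 shRNA line 2, control line 1 or control line 3 (limma adjusted p up to 0.0865).

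In the split of EWS-FLI1 shRNA lines 1, 2 and 5 from the other libraries, 5 genes serve as examples. FOS stood at 0.698, 0.625 and 1.82 RPKM in lines 1, 2 and 5, at 62.0 and 125 RPKM in lines 3 and 4, and at 28.1, 64.9 and 42.5 RPKM in the controls. EGR1 stood at 19.8, 4.58 and 5.80 RPKM in lines 1, 2 and 5, at 134 and 208 RPKM in lines 3 and 4, and at 140 to 225 RPKM in the controls. HMCN1 stood at 3.85, 8.96 and 2.33 RPKM in lines 1, 2 and 5, and at 114 to 142 RPKM in the other 5 libraries. FOSL1 and TNFRSF12A went the other way, at 18.4, 19.7 and 95.9 RPKM and at 54.3, 72.3 and 74.8 RPKM in lines 1, 2 and 5, and at no more than 1.48 and 6.06 RPKM elsewhere. None of these 5 genes passed in the comparison of the study's groups.

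Control line 2 held more COL1A1 and CTGF than the other 2 controls, and a test for admixed cells of the EWS-FLI1 shRNA lines was chosen after this was seen. To reach its COL1A1 level, 15.3% of such cells would be needed. Over the 73 genes higher in the EWS-FLI1 shRNA lines the median share needed was 2.66%, with 22 genes at 0 or less and 9 genes at or above the share for COL1A1. These genes were called with control line 2 among the controls, which favours genes with low values in it, so the test does not decide the question.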
